A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

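Total RNA from budding yeast in mid-log growth was measured on 6 Affymetrix expression arrays, 3 from wild type cells and 3 from cells carrying a deletion of VPS4. Per the labels' protocols, the cells grew at 26 °C in synthetic medium with the amino acids they required, RNA was purified on silica columns, and biotin-labelled targets came from a 3′ in vitro transcription kit. Groups and replicate numbers were taken from the sample titles, which number the wild type arrays 4, 6 and 3 and the deletion arrays 4, 5 and 6. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

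The deposited table holds log2 expression values per probe set, made with GCRMA (background correction from probe sequence, quantile normalization and a robust summary of each probe set) per the submitters' processing notes, which give no version. The values lie on a log2 scale from below 1 to above 13, and the array medians over tested probe sets lie between 9.12 and 9.15. GCRMA pulls dim probe sets together near the floor, which shrinks both their spread and their differences. No further normalization was applied before testing. The arrays' number, 3 per group, limits the precision of every comparison, and an exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1.

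Probe sets were named through the platform annotation, and 12 symbols were updated through their gene ID with a gene table of assembly R64, which was used for names and for which genes neighbour each other. Of 10928 probe sets, 7244 had 1 gene symbol, 1 had several and the others had none. The 5498 probe sets annotated to Saccharomyces cerevisiae, covering 5449 genes, were tested, and none of these carried several symbols. Another 1747 belonged to another yeast on the same array, 213 were controls and 3470 were unnamed here. Among the tested probe sets, 128 were of the kinds that can match several transcripts of a family, so members of such families are uncertain. In 1 of the 47 genes with several probe sets, some but not all of the probe sets passed the threshold. No coordinates are given because the build behind the annotation is not given in the sources used here.

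The background of each array was taken as percentile 95 of the probe sets of the other yeast. A gene whose probe set lay at or below that level on every array of a group has only a bound there, and its fold is given as at least the bright group's mean over the mean, per array, of the higher of the background and the probe set's own value.

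Differences between genotypes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, genotype as the single term, two-sided) and adjusted by Benjamini-Hochberg over all 5498 tested probe sets, with a threshold of 0.05. Differences are VPS4 deletion minus wild type on the log2 scale with the moderated standard error (SE). Errors on group means are SD with n = 3. Before the data were examined, 37 gene lists, the rule for named genes and the alternatives were fixed. Of the lists, 34 with at least 3 measured genes were tested with camera (correlation between genes preset to 0.01, Benjamini-Hochberg over the lists), using for each gene the probe set with the highest mean, and 3 lists of strain markers and mating type genes were read gene by gene. Beside camera, the correlation was estimated per list, and fry was run. The p-value of fry tests whether a list's genes move, on balance, one way, and its mixed p-value whether they change in either direction; neither compares the list with other genes. The name MLP1 in the cell wall list is shared by a nuclear pore gene, and YGK3 sits in the Rim101 list with less certainty than its other members. The ribosomal protein list, matched by name pattern, includes RPP1, a subunit of RNase P, and the proteasome list includes RPN4, a transcription factor.

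The named genes are VPS4, the 10 largest increases and 10 largest decreases among probe sets past the threshold whose groups did not overlap, up to 3 members of each list past the same criteria (or, where none passed, the member with the smallest p), and every measured strain marker and mating type gene. Outside this rule, YPR172W was named as the neighbour of VPS4, and the other genes are said to be chosen after their values were seen.

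The alternatives were no variance trend, a robust variance prior, dim probe sets left out, quantile normalization or median centring of the tested probe sets, all probe sets tested, array weights, each array left out, the title number as a block, 2 other thresholds, an estimated correlation and a rank version of camera. A change of pseudocount was not run because the table is already on the log2 scale. After the data were examined, the shared calls and list counts without wild type replicate 3, and the estimated correlation without that array, were added. The fit was tested on simulated data with the means and spreads of the 5498 probe sets and 200 changed ones: of 50 probe sets at each size, 38% were recovered at 0.25 log2, 78% at 0.5 log2, and 100% at 1 and at 2 log2, with 8 false calls among 166. In a simulation of independent genes, the 1 shifted list was called and 0 of the other lists. Both simulations drew independent noise with the same spread in both genotypes and no array standing apart. Wild type replicate 3 stood apart in the real data, so these rates need not hold there. Figures were drawn with matplotlib 3.10.9.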

Results

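The series measured the messenger RNA of Saccharomyces cerevisiae, budding yeast, on 6 arrays: 3 of wild type cells and 3 of cells without VPS4. The Vps4 protein is the ATPase that takes the ESCRT-III complex off endosomal membranes, the last step in forming the multivesicular bodies that carry membrane proteins to the vacuole. The series title places the comparison in a study of ESCRT mutants and of amino acid recycling through that pathway. Each array gave 5498 tested probe sets, of which 97.5% to 98.0% lay above the array's background.

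VPS4 (YPR173C) stood at 11.44 ± 0.04 (SD, n = 3) in wild type and at 1.49 ± 0.23 (SD, n = 3) in the deletion, where it was not above background on any array. The level was at least 760-fold lower in the deletion (limma, Benjamini-Hochberg adjusted p = 1.30e-07). All 6 arrays therefore carried the VPS4 level that their labels give. YPR172W, the neighbouring gene on 1 side, differed by 0.17 ± 0.08 (SE), which did not pass the test (limma adjusted p = 0.344).

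HSP30, a stress protein of the plasma membrane, rose 9.81-fold in the deletion, from 4.41 ± 0.61 to 7.71 ± 0.10 (SD, n = 3; limma adjusted p = 0.00393). HSP26, a small heat shock chaperone, rose 6.79-fold to 9.59 ± 0.02 (limma adjusted p = 0.00230). The aquaporin gene AQY2 rose 5.97-fold and the neighbouring reading frame YLL053C rose 4.47-fold. CHA1, which encodes the serine and threonine deaminase, rose 4.52-fold (limma adjusted p = 0.00217). IZH4, SMP1, HBN1, DIA1 and SPS100 completed the 10 largest increases, between 4.11-fold for IZH4 and 2.95-fold for SPS100.

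Among the 10 largest decreases, PRM2, PRM6, PRM3 and PRM1, which encode pheromone-regulated membrane proteins, were 4.96-fold, 4.56-fold, 4.45-fold and 4.23-fold lower. FIG1 and FUS2, which act in mating and cell fusion, were 4.21-fold and 2.98-fold lower. Reading frames of the Ty3 retrotransposon, YGR109W-A, YIL082W-A and YGR109W-B, were 2.89-fold, 2.73-fold and 2.63-fold lower, though the probe sets of YGR109W-A and YIL082W-A are of a kind that can match several copies. IME4, the mRNA adenosine methyltransferase, fell from 3.91 ± 0.63 to 2.41 ± 0.23 (SD, n = 3; limma adjusted p = 0.0477).

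In all, 155 probe sets were higher and 80 were lower in the deletion (limma, Benjamini-Hochberg over 5498 probe sets), 4.27% of those tested. Of these, 27 rose and 15 fell by at least 2-fold. At an unadjusted p under 0.05 there were 958, and the groups did not overlap for 24.8% of probe sets, against 10% by chance. The count rested on the arrays used: it was 656 higher and 556 lower without wild type replicate 3, and all 155 and 80 were called there too. It was 81 and 37 without wild type replicate 4, 67 and 36 without wild type replicate 6, 44 and 14 without deletion replicate 4, 17 and 5 without deletion replicate 5, and 37 and 10 without deletion replicate 6. Of 71 named genes that passed, VPS4 aside, 13 passed in each of these fits, HSP30, HSP26, AQY2, CHA1, RIM8 and NRG1 among them.

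**Figure D1:**
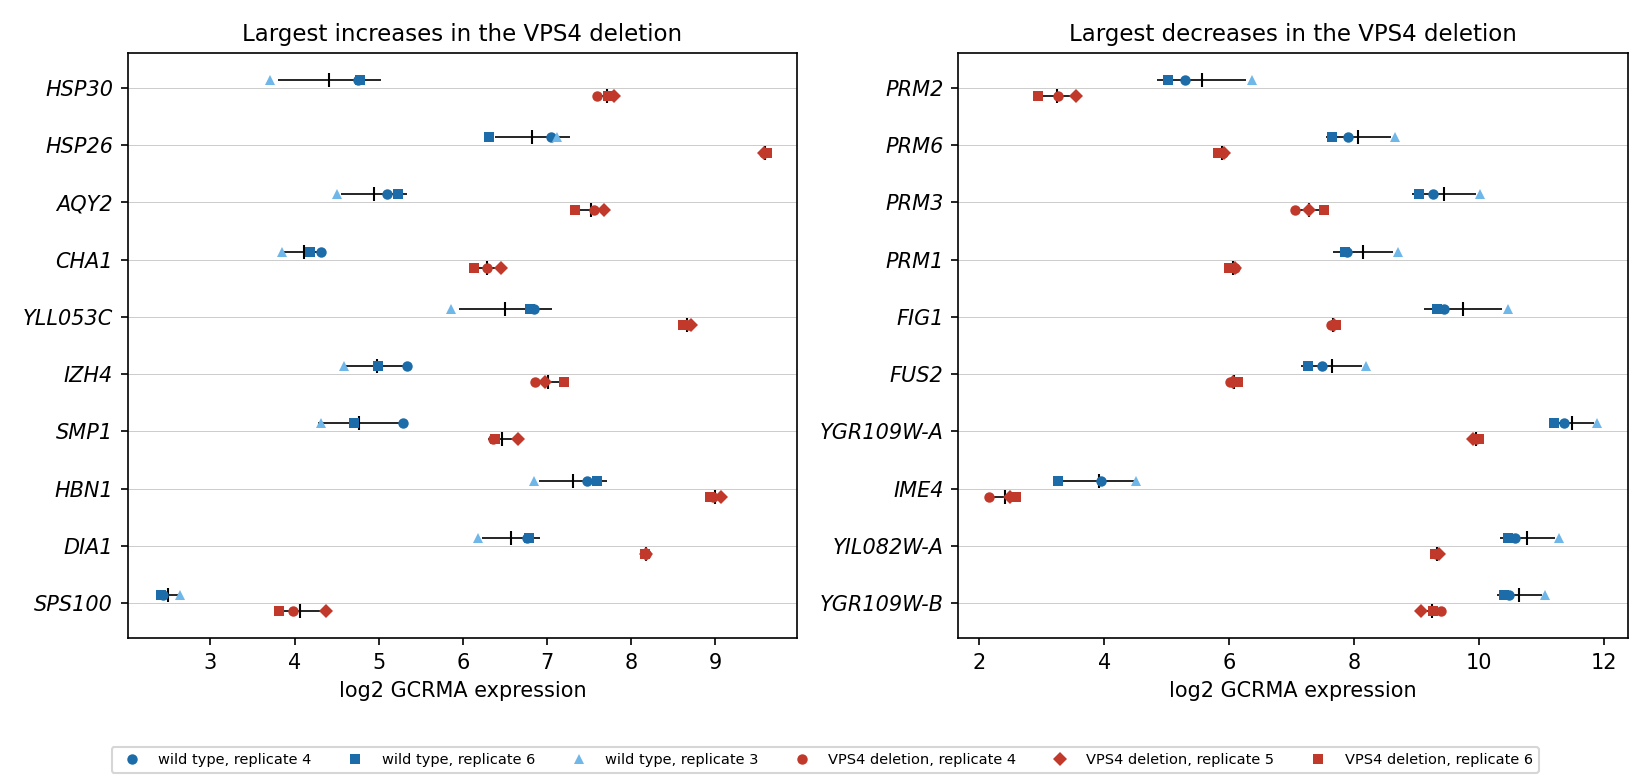
Log2 GCRMA expression (horizontal axis) of the 10 largest increases and the 10 largest decreases on each of the 6 arrays, with the mean (tick) and SD (bar, n = 3) of each genotype. The genes were selected to have no overlap between the genotypes, and HSP30 shows the widest difference of means at 3.29 log2.

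The pheromone response was the group with the widest shift. Of its 17 measured members, 14 fell, 0 rose and 3 did not pass the test. The fusion genes FUS1 and FUS2, the agglutinin anchor AGA1 and the regulator SST2 were lower, by −1.28 ± 0.16 (SE) for FUS1, −1.06 ± 0.13 for AGA1 and −0.86 ± 0.12 for SST2. The transcription factor gene STE12 fell by 0.25. GPA1, CIK1 and FUS3 differed by −0.19, −0.31 and −0.33 and did not pass. Of these genes all but FUS2 were chosen after their values were seen. Adjusted over the list alone, 17 members were lower. The median difference was −1.06 (camera adjusted p = 7.67e-20; adjusted p = 0.357 with an estimated correlation). Wild type replicate 3 stood above the other wild type arrays by a median of 0.49 log2 in this list, and without it 17 members were lower, with a median of −0.90.

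Genes that mark mating type showed alpha cells on every array. MF(ALPHA)1 stood at 13.08 ± 0.03 in wild type and 13.04 ± 0.03 in the deletion (SD, n = 3), and STE3 at 11.94 ± 0.13 and 11.74 ± 0.04. Among the 4 alpha genes, MF(ALPHA)2 and SAG1 fell, by 0.31 and 0.63, and the other 2 did not pass; STE3 also fell without wild type replicate 3 (limma adjusted p = 0.00641). Among the 7 genes of a cells, which were dimmer, STE2 fell by 1.01 (limma adjusted p = 0.0101) and MFA2 by 0.88 (limma adjusted p = 0.0323). AGA2 differed by −1.55 ± 0.53 (SE) and did not pass (limma adjusted p = 0.194); wild type replicate 3 differed by −1.94 log2 from the other wild type arrays. MFA1, STE6, BAR1 and ASG7 did not pass, with a difference of 0.02 ± 0.11 (SE) for STE6. Once replicate 3 was left out, AGA2 and MFA1 fell as well, by −2.19 ± 0.17 (SE; limma adjusted p = 1.68e-05) and −0.43 ± 0.11 (0.0209), so that 4 of the 7 were lower.

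Several general stress genes, targets of Msn2 and Msn4, rose in the deletion. Of 26 measured members, 5 rose, 0 fell and 21 did not pass, and adjusted over the list alone 10 rose. Besides HSP26, the HSP70 chaperone genes SSA3 and SSA4 rose by 1.01 ± 0.10 and 0.72 ± 0.06 (SE). The median difference was 0.35 (camera adjusted p = 3.83e-07; adjusted p = 0.357 with an estimated correlation). Wild type replicate 3 lay above the other wild type arrays by a median of 0.29 in this list, and without it 20 members rose and 2 fell. DDR2, chosen after its values were seen, differed by −2.31 log2 between that array and the other wild type arrays and did not pass between genotypes (limma adjusted p = 0.455).

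The Rim101 list joins genes of the pathway and alkaline pH targets. Of its 12 measured genes, 3 rose, 0 fell and 9 did not pass, and the count adjusted over the list alone was also 3. Without wild type replicate 3, 4 rose and 1 fell. RIM8, an arrestin-like protein of the pathway, rose by 1.30 ± 0.08 (SE; limma adjusted p = 0.00197), NRG1, a repressor, by 0.85 ± 0.07, and SMP1, a MADS box factor, by 1.70 ± 0.24. The median of the list was 0.03 and its mean 0.33 (camera adjusted p = 0.0413; adjusted p = 0.425 with an estimated correlation). The list's call ended in 10 of 17 alternatives, among them without wild type replicate 3 (camera adjusted p = 0.0765), without wild type replicate 6 (0.0550), without deletion replicate 4 (0.0575) and without deletion replicate 5 (0.0752).

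Among 11 vacuolar hydrolase genes, PRB1, the vacuolar protease B gene, rose by 0.52 ± 0.05 (SE; limma adjusted p = 0.00582), 10 did not pass and 0 fell; adjusted over the list alone 3 rose. The median was 0.13 (camera adjusted p = 0.0154; adjusted p = 0.492 with an estimated correlation), and the call ended without wild type replicate 4 (camera adjusted p = 0.0723). Without wild type replicate 3, 6 members rose. ATG8, the ubiquitin-like protein of autophagosomes, rose by 0.44 ± 0.04, and the other 26 autophagy genes did not pass, whereas 6 rose and 1 fell without wild type replicate 3. BTN2 rose by 0.52 ± 0.07 and was the 1 called gene of 15 in the list of vacuolar amino acid transport, where 14 did not pass. Of the 18 genes of the vacuolar ATPase, 0 passed. Without wild type replicate 3, 3 genes of the transport list and 1 of the ATPase list rose.

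In the ESCRT machinery itself, 3 of 19 measured genes rose, 0 fell and 16 did not pass, and adjusted over the list alone 4 rose. HSE1 rose by 0.33 ± 0.06 (SE), DID2 by 0.21 ± 0.04 and VPS60 by 0.21 ± 0.04; the last 2 encode proteins of the ESCRT-III family. The list did not pass as a whole (camera adjusted p = 0.175). PEP12, the endosomal syntaxin, rose by 0.59 ± 0.05 and was the 1 called gene of 23 in endosome and vacuole traffic. Among 24 genes of ubiquitin and the Rsp5 adaptors, the polyubiquitin gene UBI4 rose by 0.28 ± 0.05, TRE1 fell by 0.22 and 22 did not pass. With wild type replicate 3 left out, 5 ESCRT genes and 3 traffic genes rose, and 3 genes of the ubiquitin list rose and 3 fell.

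In leucine, isoleucine and valine synthesis, 3 of 12 measured genes fell, 0 rose and 9 did not pass, and adjusted over the list alone 7 fell. LEU1, BAT1 and ILV3 fell by 0.42, 0.18 and 0.15. The list's median difference was −0.07 (camera adjusted p = 0.000327, or 0.357 with an estimated correlation). In sulfur amino acid synthesis 3 of 22 fell, 0 rose and 19 did not pass, with 8 lower when adjusted over the list alone. The sulfate permease gene SUL1 fell by 0.27, MET8 by 0.21 and MET10 by 0.19. The sulfur list's median difference was −0.11 (camera adjusted p = 0.000150, or 0.523 with an estimated correlation). In arginine synthesis, ARG3 fell by 0.62, ARG8 fell by 0.26, CPA1 rose by 0.18 ± 0.03 (SE) and 4 did not pass (camera adjusted p = 0.367). Of the lysine list (8 genes), the list of serine and related amino acids (18) and the regulators of general amino acid control (13), 0 genes passed. LEU2, HIS3 and LYS2, synthesis genes that also serve as strain markers, were kept out of these lists. The calls in these lists moved when wild type replicate 3 was left out: 2 rose and 6 fell in leucine, isoleucine and valine synthesis, 1 rose and 7 fell in sulfur amino acid synthesis, and 3 rose and 2 fell in arginine synthesis. In the same fit 1 lysine gene rose, 3 genes of the serine list rose and 3 fell, and 3 regulators of general amino acid control fell. None of the 19 genes of histidine and aromatic synthesis passed (limma), while 7 rose and 1 fell without wild type replicate 3, which lay 0.22 above the other wild type arrays in that list's median.

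Among 20 amino acid and peptide permease genes, DIP5, the dicarboxylic amino acid permease, fell by 0.82, ALP1 and the peptide transporter gene PTR2 rose by 0.74 ± 0.15 and 0.53 ± 0.08 (SE), and 17 did not pass; adjusted over the list alone 3 rose and 3 fell, and without wild type replicate 3, 5 rose and 4 fell. GAP1, the general amino acid permease, chosen after its values were seen, differed by −0.71 ± 0.17 and did not pass (limma adjusted p = 0.0784), but fell without wild type replicate 3, which was 0.65 above the other wild type arrays. Of 22 targets of nitrogen catabolite repression, 4 rose, 0 fell and 18 did not pass, and adjusted over the list alone 5 rose and 2 fell; without wild type replicate 3, 8 rose and 4 fell. The proline oxidase gene PUT1 rose by 0.76 ± 0.12 and the allantoate permease gene DAL5 by 0.61 ± 0.08. DAL80 was at least 1.35-fold higher, since it was not above background in wild type. As a list these targets did not pass camera (camera adjusted p = 0.142) but moved one way on balance by fry (fry adjusted p = 0.0167).

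In the unfolded protein response, HAC1 rose by 0.16 ± 0.03 (SE) and 17 of 18 did not pass. The median difference of that list was only 0.04 (camera adjusted p = 0.0339, or 0.357 with an estimated correlation). That list's call ended in 6 of 17 alternatives, among them without wild type replicate 4 (camera adjusted p = 0.130), without deletion replicate 5 (0.0879) and without the variance trend (0.0505). Of 19 cell wall genes, 3 rose and 2 fell, with CWP1 lower by −0.55 ± 0.04, KDX1 by −0.46 ± 0.07 and CRH1 higher by 0.18 ± 0.03. In ergosterol synthesis ERG4, ERG27 and ERG25 rose by 0.22, 0.19 and 0.09, and 22 did not pass. In the tricarboxylic acid cycle FUM1, IDH2 and IDH1 fell by 0.18, 0.14 and 0.11, and 15 did not pass. THI4 rose by 1.28 ± 0.24 and THI13 fell by 0.54 among 16 thiamine genes. PHM8 rose by 1.24 ± 0.18 among 15 phosphate genes, ZRC1 by 0.19 ± 0.03 among 10 zinc genes and FRE3 by 0.75 ± 0.14 among 25 iron genes. RPS14B fell by 0.21 among the 128 genes of the ribosomal protein list, and SPO11 fell by 0.47 among 16 sporulation genes. The hexose, ribosome biogenesis, respiratory chain, NAD and proteasome lists held 0 called genes (limma). Adjusted over the list alone, 2 autophagy genes rose, 5 cell wall genes rose and 4 fell, 3 zinc genes rose and 2 fell, 1 gene of the tricarboxylic acid cycle rose and 3 fell, 3 sporulation genes fell, and 1 NAD gene rose and 1 fell. Without wild type replicate 3, 20 of 53 ribosome biogenesis genes, 10 of 30 respiratory chain genes and 8 of 16 hexose genes fell, while 2 hexose genes rose; that array differed from the other wild type arrays by a median of −0.24, −0.16 and −0.57 in these lists. In that fit 4 genes of the unfolded protein response rose, 5 cell wall genes rose and 4 fell, 7 ergosterol genes rose and 1 fell, 3 genes of the tricarboxylic acid cycle rose and 4 fell, and 3 zinc genes rose and 4 fell. The higher and lower counts there were 2 and 2 for thiamine, 1 and 2 for phosphate, 1 and 3 for the ribosomal protein list, 0 and 4 for sporulation and 1 and 1 for NAD.

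**Figure D2:**
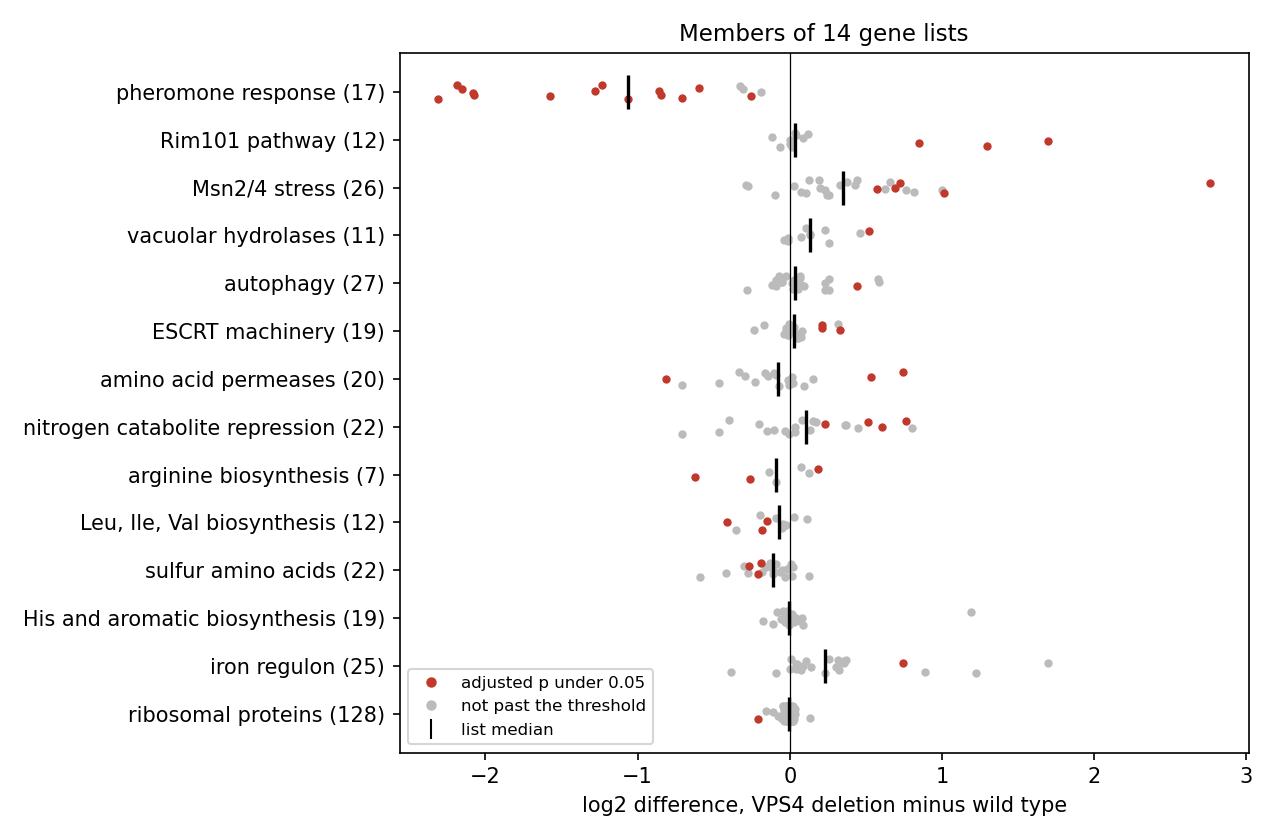
Log2 difference (horizontal axis, VPS4 deletion minus wild type) of each measured member of 14 gene lists, with the number of members in brackets, the list median as a bar and members past the threshold in red. The pheromone response lies to the left with a median of −1.06, and the ribosomal proteins lie close to 0.

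Of the 34 lists, camera called 7, of which 4 were higher and 3 lower. With a correlation estimated per list, 0 were called, the smallest adjusted p was 0.357, and 4 had an unadjusted p under 0.05. By fry, 5 lists moved one way on balance and 18 changed in either direction. The 5 were the pheromone, stress, Rim101, leucine, isoleucine and valine, and nitrogen catabolite repression lists (fry adjusted p = 0.0167 for each). Of the lists that camera called, sulfur amino acid synthesis (fry adjusted p = 0.254), vacuolar hydrolases (0.139) and the unfolded protein response (0.139) did not pass fry. The median, mean and camera direction differed in sign for 6 lists, all uncalled: histidine and aromatic synthesis, phosphate, zinc, respiratory chain, tricarboxylic acid cycle and vacuolar amino acid transport. The lists not called had camera adjusted p-values from 0.0627 to 0.948. Each of the other 9 splits of the 6 arrays into 3 and 3 also called at least 7 lists.

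Strain marker genes were read one by one. LEU2 fell by 0.34 (limma adjusted p = 0.00309) and HIS3 rose by 0.25 ± 0.03 (SE; limma adjusted p = 0.00730). URA3, ADE2, LYS2 and MET17 did not pass, although URA3 rose by 0.35 ± 0.07 (SE) without wild type replicate 3 (limma adjusted p = 0.00634). SUC2 was not above background in either genotype.

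Replicates of the deletion were closely alike, and wild type replicate 3 stood apart. Over the tested probe sets, Pearson's r across genes, which are not independent replicates, was 0.9991 between wild type replicates 4 and 6 and 0.9988 to 0.9991 among the deletion arrays, but 0.9926 between replicate 3 and either of the other wild type arrays. Replicate 3 differed by over 1 log2 from their mean in 73 probe sets, 49 lower and 24 higher, while replicates 4 and 6 differed by that much in 0. Wild type replicates 4 and 6 correlated more closely with the deletion arrays (r from 0.9936 to 0.9943) than with replicate 3. Between replicate 3 and the deletion arrays r was 0.9895 to 0.9899. The median SD was 0.0773 in wild type and 0.0455 in the deletion. The first principal component held 58.1% of the variance and set the wild type arrays (6.6 to 15.2) apart from the deletion arrays (−10.0 to −9.2). The next held 31.5% and set wild type replicate 3 (12.0) apart from replicates 4 and 6 (both −9.1), with the deletion arrays between them. In replicate 3 the iron regulon had a median difference of −0.80 log2 from the other wild type arrays, with −4.62 for TIS11 and −3.10 for FIT2, both chosen after their values were seen. FRE3 was the 1 iron gene that rose in the deletion, and without replicate 3 the list had 2 higher and 5 lower. As a list the iron genes did not pass (camera adjusted p = 0.0627), and the call turned on the processing, upward in 7 alternatives and downward in 1.

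**Figure D3:**
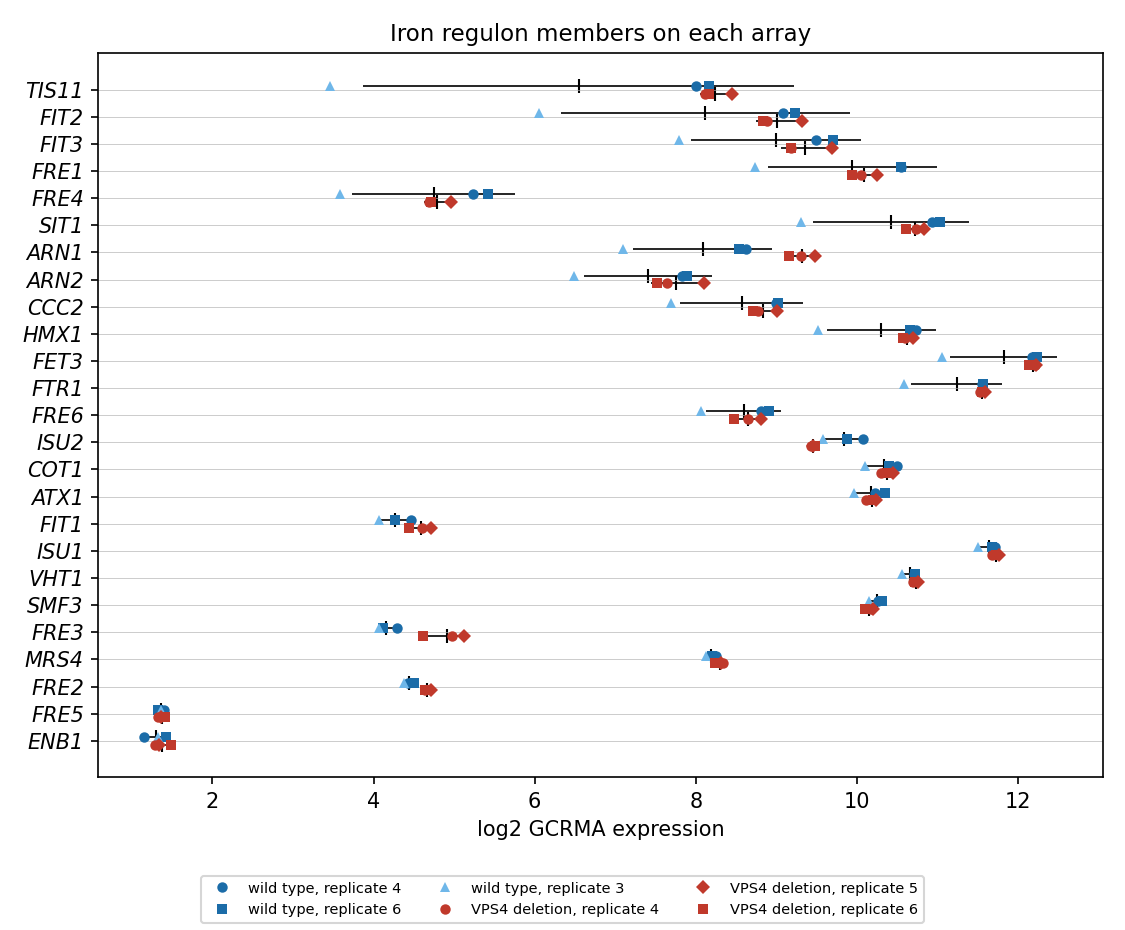
Log2 GCRMA expression (horizontal axis) of the 25 measured iron regulon genes on each of the 6 arrays, with the mean (tick) and SD (bar, n = 3) of each genotype. Wild type replicate 3 lies to the left of the other arrays for TIS11, FIT2 and FIT3, all chosen after their values were seen.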

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

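The tests of explanations in this part were chosen after the results they address had been seen, except that leaving out each array and quantile normalization had been chosen before the data were examined; what each explanation predicts was written down after its value was known. The measure of RNA degradation replaced an earlier one, a count of control genes above the range of the other arrays, after the value of that count was known, and the 1 log2 it is held to was set after its own value was known.

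Outside the tested genes, 12 probe sets with no gene name here were higher in the VPS4 deletion and 2 were lower (limma, adjusted over all probe sets but controls), a signal in data that the comparisons did not use. The widest difference among them was between 7.99 ± 0.34 in wild type and 9.62 ± 0.01 in the deletion (SD, n = 3).

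Wild type replicate 3 differed from the other wild type arrays by over 1 log2 in 73 probe sets. A deletion sample carrying a wild type label is ruled out by VPS4, which stood at 11.46 in that array. The probe sets of the other yeast had a median of 1.44 in that array, inside the range of the other arrays, 1.42 to 1.45. The processed values thus held no shift in background. Whether the raw background shifted cannot be decided, because the values were already background-corrected and quantile-normalized. RNA degradation across the sample, as the cause of differences over 1 log2, is argued against by the 3′ over 5′ ratio of 4 control genes, which lay 0.0278 log2 above the mean of the others (their SD 0.0131). It was just beyond their range, so a slight degradation, or one confined to other transcripts, is not excluded. A different nutrient state of that culture stays open and untested: the iron list lay at percentile 0 of random lists matched on expression, but it was picked because it was seen to move in that array. The hexose, ribosome biogenesis and respiratory chain lists also lay at percentile 0, and the histidine and aromatic, stress and pheromone lists at 100. The labels name no such difference.

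The fall of the pheromone response genes did not come from wild type replicate 3 alone, as 17 members fell without it. After quantile normalization of the tested probe sets 14 fell. The deposited values were already quantile-normalized, and repeating that step moved no difference between genotypes by more than 0.128 log2. It therefore cannot decide whether array scaling contributed. A small share of a cells in the wild type cultures could raise both pheromone genes and genes of a cells. It cannot be told apart from an effect of the deletion here, because 2 of the 7 genes of a cells fell, and 4 without wild type replicate 3, while STE6 differed by 0.02 ± 0.11 (SE) and did not pass, nor did ASG7 and BAR1. These genes were dim, and the rise that such a share would give each of them is not known here. The genotype itself remains open as the biological explanation.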

How the results depend on the processing

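The estimated correlation without wild type replicate 3 was chosen after the data were examined; the other alternatives were planned. Without the variance trend, with a robust prior, without dim probe sets, with quantile normalization, with median centring or with all probe sets tested, the counts of higher and lower probe sets stayed within 1.5 times 155 and 80. Array weights gave 600 higher, 436 lower and 12 lists, with a weight of 0.143 for wild type replicate 3. Leaving out 1 array gave 17 to 656 higher and 5 to 556 lower, and 5 to 12 lists. A threshold of 0.01 left 49 higher and 18 lower, and a 2-fold minimum left 27 and 15, by construction. With an estimated correlation 0 lists were called, and 0 with wild type replicate 3 left out as well. Estimating the correlation also makes camera use the 4 residual degrees of freedom, not the far larger number set by the gene count. The share of each in the loss of calls was not tested, but a higher correlation cannot account for the loss in every list. In the unfolded protein response the estimate was −0.00853, under the preset 0.01, yet the unadjusted camera p rose from 0.00599 to 0.0410. In the other called lists the estimate lay above the preset, from 0.0314 for the Rim101 list to 0.697 for the pheromone response. Histidine and aromatic synthesis, uncalled with a downward direction, was called upward with array weights (camera adjusted p = 0.0394) and without wild type replicate 3 (0.00360, the lowest of the leave-outs, with 0.925 the highest). With the title number as a replicate block the counts were 478 higher, 380 lower and 12 lists. Wild type replicate 3 and deletion replicate 5 share their number with no other array. The genotype difference in that fit therefore rests on arrays 4 and 6 of each genotype. Histidine and aromatic synthesis was again upward (camera adjusted p = 0.00338), the call of the unfolded protein response ended (0.0647), and the iron list turned downward (0.0130). The iron list, uncalled and upward, was called upward with quantile normalization (0.0291), median centring (0.0172), ranks (0.0204), without wild type replicate 4 (0.00397) or 6 (0.00149) and without deletion replicate 4 (0.0429) or 6 (0.0414). Also uncalled, but called in at least 1 alternative, were the lists of the vacuolar ATPase, ribosomal proteins, general amino acid control, serine and related amino acids, hexose, ribosome biogenesis, ergosterol, respiratory chain and proteasome. Deviations of arrays sharing a number correlated at 0.021 and −0.059, and the numbers were not used as pairs in the main fit. Whether the numbers pair the samples stays undecided, because the wild type deviations were taken from a mean that includes the outlying replicate 3. Over the alternatives for named genes, 0 called genes changed sign. Some 97.5% to 98.0% of tested probe sets lay above background, and 84 were below it in both genotypes.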

Other observations

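The test of Ty3 below and the genes named in the next paragraph were chosen after their values were seen; the splits of the arrays were planned, but their predictions were written after the counts were known.

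Outside the lists and the named genes, 112 probe sets rose and 38 fell (limma, Benjamini-Hochberg). Among those that rose were CMK2, a calmodulin-dependent kinase gene, by 0.88 ± 0.04 (SE), DDR48 by 0.93 ± 0.07, the glycogen branching enzyme gene GLC3 by 0.91 ± 0.18, the phospholipase B genes PLB1 and PLB2 by 0.57 ± 0.06 and 1.05 ± 0.11, and YPT53, an endosomal Rab GTPase gene, by 1.46 ± 0.22. Both fatty acid synthase genes rose slightly, FAS1 by 0.10 ± 0.02 and FAS2 by 0.12 ± 0.02. Among those that fell were the uracil permease gene FUR4 by −0.78 ± 0.13, the regulator TEC1 by −0.37 ± 0.06 and AFR1, which acts in mating projections, by −0.61 ± 0.09.

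Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 235 called probe sets, and the highest of the others gave 0. For gene lists, 10 of the 10 splits gave at least the 7 called between the genotypes, and the highest of the others gave 17. For probe sets, the splits are too few for a share under 0.05. For lists, every split reached 7, so the count of called lists does not set the genotypes apart from other groupings of the arrays.

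A hypothesis for the fall of the Ty3 reading frames is shared control with the pheromone response genes. In wild type replicate 3, where the pheromone genes were high, the median difference of the 3 Ty3 probe sets from the other wild type arrays lay at percentile 98.6 of all tested probe sets. The value decides nothing: the probe sets of YGR109W-A and YIL082W-A can match several copies of the element, so the 3 need not be separate measurements, they were ranked against single probe sets, and they were picked as large decreases from a wild type mean that included that array. The hypothesis stays untested.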
